A study of Mus musculus with 2 samples.

How the data were processed

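The samples were 2 single-cell RNA libraries of mouse spinal cord, sham and 3 days post injury (3 dpi), each a pool of 5 male and 5 female C57BL/6 mice aged 8 weeks. Per the labels, a piece of cord of 8 mm around the injury site was dissociated, cells were captured with the 10X Chromium 3′ kit v.3, and libraries were read as 150-base pairs on an Illumina NovaSeq instrument. The kind of injury is not given in the sources used here. The deposited tables held 1 raw UMI count per gene and barcode, for 22480 gene symbols in the same order in both tables. The submitters' processing notes name Cell Ranger and Seurat without versions or roles, and which cells they kept is not given in the sources used here. The notes give GRCh38, a human build, although the deposited gene symbols are mouse symbols: 22164 of the 22480 were found among the mouse GENCODE symbols and 316 were not. No gene positions were used.

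No table held mitochondrial genes (0 of 22480 rows), so the filters of at most 20% or 10% mitochondrial UMIs could not be run. Cells needed at least 200 genes and 500 UMIs, which left 10126 of 10138 sham and 13584 of 13594 3 dpi barcodes. Barcodes held 462 to 97200 UMIs in sham and 466 to 76237 at 3 dpi. Doublets were scored per library against 2 simulated doublets per cell by the share of simulated neighbours, and the expected number (0.8% per 1000 cells) with the highest scores was removed: 820 sham (8.10%) and 1476 3 dpi cells (10.9%). The score threshold was passed by 64.2% and 70.1% of simulated doublets. Of kept cells with any sex-linked UMI, 11.2% in sham and 4.83% at 3 dpi held both Xist and Y-linked UMIs, against 37.8% and 24.7% of the removed cells, so doublets or free RNA remained. Kept cells numbered 9306 and 12108, with median depths of 5259 and 8420.5 UMIs.

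Counts were scaled to 10000 per cell and logged, and 2000 variable genes were chosen within each library over 20 expression bins, without the genes of the response lists, ribosomal and sex-linked genes. Both libraries were clustered together from 30 principal components and a graph of 15 shared neighbours with the Leiden method at resolution 1.0, without batch integration, which gave 30 clusters. A cluster took the class, of 17 with fixed markers, whose markers had the highest mean log2 fold over the median cluster, if at least 3 markers were 2-fold higher and seen in 10% of its cells and its 10 leading genes did not go against the name. Such classes are called X-like and come from rebuilt clusters. The comparison with the median cluster, and the rule that left a cluster unnamed when a 2nd class lay within 1 log2 unit with 50% of its markers 2-fold higher, were set after the data had been seen. 12 classes had a cluster and 5 clusters stayed unnamed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.

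Cells are not replicates, so UMIs were summed per class and library and given per 1000000 UMIs of that class and library (CPM). Shares of cells carry Clopper-Pearson intervals, summed counts exact Poisson intervals and ratios of counts exact conditional intervals, all at 95%. These intervals cover counting error only, and those of summed counts and their ratios treat each UMI as independent, which leaves out the spread between cells. With 1 library per group there was no test, no p-value and no check against replicates. Log2 ratios are of 3 dpi over sham with 10 CPM added to both, and folds are ratios of CPM. A gene at 0 UMIs in 1 library was given as at least N-fold against a floor of 3 counts over the class, and a share of 0 cells is given with the limit that 3 cells would set. The 4 classes with at least 50 cells in both libraries were compared: microglia-like (9081456 UMIs in sham, 31192153 at 3 dpi), oligodendrocyte-like (43337989 and 19026522), precursor-like (1476981 and 11319074) and endothelial-like cells (5769329 and 6655138). Median-of-ratios scaling shifted log2 ratios by 0.12, 0.02, 0.26 and 0.26 in these classes relative to CPM.

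The sample groups, comparisons, cell markers, 27 gene lists, named-gene rule and most alternatives were fixed before the data were examined. A list member was measured at 20 CPM or more in at least 1 library. It was called higher or lower at a 2-fold ratio with 10 CPM added to both libraries, which is a size rule. A list needed 4 measured members, and 78 pairs of list and class had them. The percentile of a list median was taken among 10000 random lists matched on size and expression, as a description of these libraries. In 11 of these pairs a member had 0 UMIs in 1 library, and with such members at the floor the medians moved by at most 0.27 (the matrix list of precursor-like cells, from 1.81 to 1.55). Of 366 list genes, 6 were absent from the tables: Clec7a, Mbpos, Madcam1 and 3 newer names of ATP synthase genes whose older names were present. Named genes needed 100 CPM, 20 UMIs and 10% of the level in the highest class, with ribosomal and sex-linked genes left out, and the 12 highest and 12 lowest log2 ratios in microglia-like and the 6 highest and 6 lowest in the other compared classes were taken, 60 in all, some of which are not reported here. Other genes are members of the fixed lists, chosen as examples after their values were seen.

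Cycling cells had at least 2 UMIs over Mki67, Top2a, Cdk1, Ccnb1, Birc5, Cenpf, Tpx2, Ube2c, Pclaf and Ccna2 after each cell was thinned to 1000 UMIs with a fixed seed, with shallower cells left out. Male-derived cells held a UMI of 4 Y-linked genes and none of Xist, female-derived cells the reverse. The alternatives were a stricter filter (500 genes and 1000 UMIs, leaving 9890 and 12719 cells), doublets kept, Leiden resolutions 2.0 and 0.5, response genes kept for clustering, male- or female-derived cells only, median-of-ratios scaling, the mean of cells' own CPM, subtraction of 5% of UMIs as free RNA with the library's profile, 1 CPM added in place of 10, list members with any UMI, cycling calls unthinned, and cycling calls at 3 UMIs. Counting cluster 15 as microglia-like, cluster 17 as macrophage-like and cluster 19 as endothelial-like, and calling sex after thinning each cell to 1000 UMIs for the microglia share, were alternatives added after the data had been seen.

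The steps were tested on simulated data in which 200 genes per class were raised or lowered. These genes were drawn from those with a mean of at least 50 CPM, so changes in genes between 20 and 50 CPM were not simulated. All genes changed 3-, 4- or 8-fold reached the 2-fold size rule in the right direction, except 1 size in precursor-like cells, where 97.0% of 33 genes lowered 3-fold did. Of 5273 to 7237 unchanged measured genes per class, 0% reached it. Only counting noise was simulated, so this says nothing about differences between libraries or in the mix of cells. Of 100 random lists of unchanged genes per class, 0, 4, 1 and 5 lay outside the central 95 percentiles, and the intervals held the true value in 95.7%, 96.8% and 95.7% of 2000 draws. Classes with fewer than 50 cells in a library were left out of the comparison of genes because their sums rest on too few cells. Reads were not realigned, since only the deposited count tables were used here.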

Results

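Gene expression was measured in single cells of mouse spinal cord with droplet libraries that count unique molecular identifiers (UMIs). There were 2 libraries, 1 from sham animals, the control without cord injury, and 1 from animals 3 days post injury (3 dpi). Each library pooled cells of 5 male and 5 female C57BL/6 mice aged 8 weeks. The sham library held 76889038 UMIs in 10138 barcodes, with a median of 5522 UMIs and 2274.5 genes per barcode. The 3 dpi library held 149291783 UMIs in 13594 barcodes, with a median of 9117 UMIs and 2698 genes. After filters and removal of called doublets, 9306 sham and 12108 3 dpi cells remained. Each group was 1 library, so there was no replicate, no test was made, and library batch and injury cannot be told apart. Intervals in brackets are 95% intervals that cover counting error only, not the spread between mice or libraries. Those of summed UMIs and their ratios also leave out the spread between cells.

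The 1st comparison asked how the cell composition of the tissue around the injury site differed between sham and 3 dpi. Cells with markers of blood-derived leukocytes made up 42.3% [41.4 to 43.1] of 3 dpi cells and 0.398% [0.280 to 0.548] of sham cells. Monocyte/macrophage-like cells were 3473 of 12108 cells at 3 dpi (28.7% [27.9 to 29.5]) and 10 of 9306 in sham (0.107% [0.0515 to 0.198]), a 267-fold [145 to 557] higher share. Neutrophil-like cells, the granulocytes that enter tissue early after damage, were 12.2% [11.6 to 12.8] at 3 dpi and 0.161% [0.0902 to 0.266] in sham. B cell-like cells (0.743% at 3 dpi and 0.0322% in sham, 90 and 3 cells) and T or NK cell-like cells (0.652% and 0.0967%, 79 and 9 cells) were also more frequent at 3 dpi. With a stricter cell filter or with doublets kept, B and T or NK cell markers fell together in an unnamed mixed cluster. The shares of these classes were not compared across settings. Fibroblast-like cells, which lay down collagen matrix, were 5.29% [4.89 to 5.70] at 3 dpi and 0.204% [0.123 to 0.319] in sham, a 25.9-fold [16.4 to 43.3] higher share.

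Among cells resident in the cord, oligodendrocyte-like cells, the myelin-forming cells, were 46.8% [45.8 to 47.9] of sham and 15.7% [15.1 to 16.4] of 3 dpi cells, a 2.98-fold lower share. Endothelial-like cells were 15.1% [14.4 to 15.8] in sham and 3.13% [2.83 to 3.46] at 3 dpi, a 4.82-fold lower share. Pericyte- or smooth muscle-like cells, which wrap vessels, were 513 cells in sham (5.51% [5.06 to 6.00]) and 5 at 3 dpi (0.0413% [0.0134 to 0.0963]). This class was the 2nd class of fibroblast-like cluster 21, with 19 sham and 204 3 dpi cells (mean log2 folds 3.67, against 5.63 for fibroblast). Its genes also led unnamed cluster 24 (31 sham and 88 3 dpi cells), while unnamed cluster 19, mixed with endothelial markers, held 321 sham cells and 1 at 3 dpi. How far naming set the pericyte and fibroblast shares was not tested. Oligodendrocyte precursor-like cells were 3.01% [2.67 to 3.38] in sham and 7.21% [6.76 to 7.69] at 3 dpi, a 2.40-fold [2.09 to 2.75] higher share. Microglia-like cells, the resident phagocytes of the cord, were 23.5% [22.6 to 24.3] in sham and 17.8% [17.1 to 18.5] at 3 dpi. Border-associated macrophage-like cells were 48 and 12 cells, and neuron-like cells 16 and 11 cells. The border-associated counts depended on the clustering. They were 52 and 52 with a stricter cell filter and 49 and 120 with response genes kept for clustering. Finer clusters again gave 48 and 12, and no cluster took this name with coarser clusters or doublets kept. Among the named classes other than leukocytes (8823 sham and 5982 3 dpi cells), the share of microglia-like cells was higher at 3 dpi (24.8% and 36.1%), as were those of precursor-like (3.17% and 14.6%) and fibroblast-like cells (0.215% and 10.7%). In the same denominator the shares of oligodendrocyte-like (49.4% and 31.8%), endothelial-like (15.9% and 6.34%) and pericyte-like cells (5.81% and 0.0836%) were lower at 3 dpi.

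These shares are of cells that survived dissociation and were captured, after removal of 8.10% of sham and 10.9% of 3 dpi cells as doublets, and median depth differed between libraries (3821 and 13551 UMIs in microglia-like, 3219 and 12478 in endothelial-like, 2426 and 1037 in neutrophil-like cells). The lower microglia share did not hold in all settings: its log2 ratio was -0.40 in all cells, 0.13 in male-derived cells and -0.06 with doublets kept. Sex calls need UMIs and favour deeper cells, and 696 of 2184 sham and 404 of 2157 3 dpi microglia-like cells carried no UMI of these genes. With each cell thinned to 1000 UMIs before the call the log2 ratio was -0.589 in male- and -0.293 in female-derived cells. In male-derived cells called without thinning, the log2 ratios of the macrophage-like (8.06), neutrophil-like (6.24), fibroblast-like (4.69) and endothelial-like (-2.27) shares were 6.70, 4.55, 5.66 and -1.68. The macrophage log2 ratio was 5.54 with coarser clusters and 9.16 in female-derived cells, and the neutrophil log2 ratio was 5.41 with a stricter cell filter. A naming threshold set after the data had been seen left clusters 15 and 19 without a class. Clusters 17, 23 and 24 stayed unnamed because they had leading genes of another class. Clusters 15, 17, 19, 23 and 24 held 0%, 0.0107%, 3.45%, 0.999% and 0.333% of sham cells, where 0 of 9306 cells allows up to 0.0322%, and 4.04%, 3.34%, 0.0083%, 0.215% and 0.727% of 3 dpi cells. No cluster was named astrocyte-, dendritic- or ependymal-like.

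**Figure D1:**
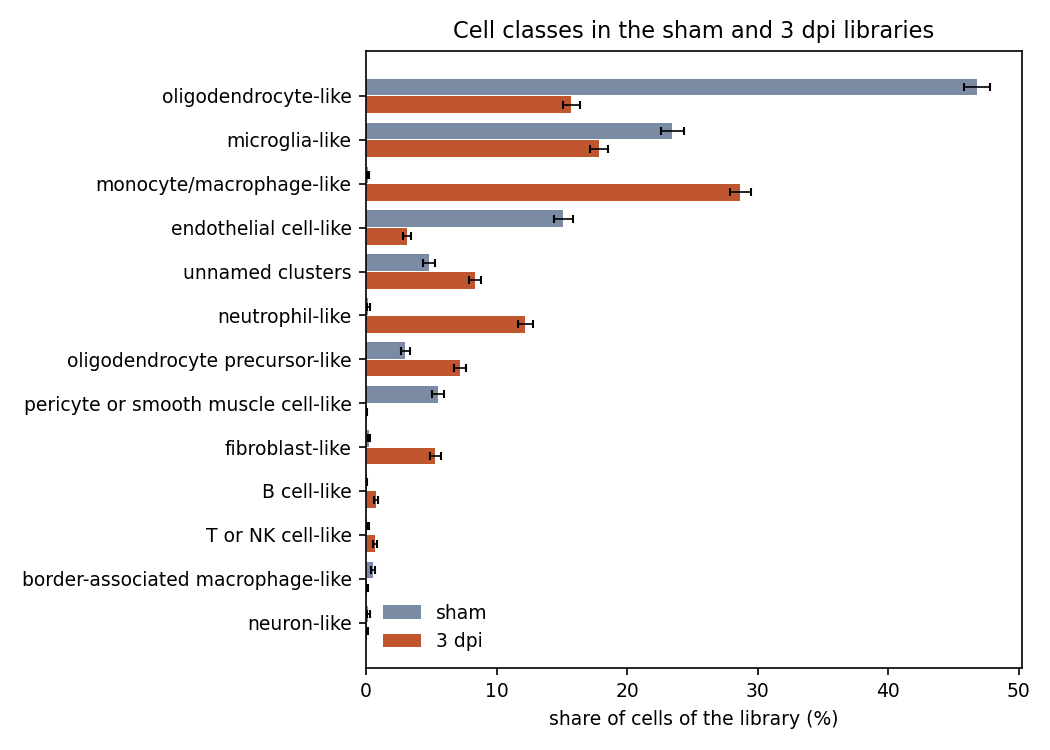
Percent of kept cells in each marker-named class for the sham (9306 cells) and 3 dpi (12108 cells) libraries, 1 library per group, with 95% Clopper-Pearson intervals as bars. Macrophage-like cells stand at 0.107% in sham and 28.7% at 3 dpi, and pericyte-like cells at 5.51% and 0.0413%.

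The 2nd comparison asked how expression within a class differed between the libraries, and microglia-like cells were compared first. Of the 14 measured microglia homeostatic genes, 12 were at least 2-fold lower at 3 dpi and 0 higher, with a median log2 ratio of -2.48, below all 10000 random lists. Most genes of this list, and of the myelin and precursor lists below, were also markers used to name the class, as were some barrier genes. A cluster that had lost these markers could not have taken the name, so the medians depend on the naming. With unnamed cluster 15 counted as microglia-like, the homeostatic median was -2.65. P2ry12, the purinergic receptor of surveying microglia, stood at 1612 UMIs per 1000000 UMIs of the class (CPM) [1586 to 1638] in sham and 103 [99.4 to 107] at 3 dpi, a 15.7-fold lower level. The lectin Siglech was 35.5-fold lower (890 and 25.04 CPM), the transcription factor Sall1 9.87-fold lower (228 and 23.2 CPM) and Tmem119 4.78-fold lower (1198 and 251 CPM). Fcrls (log2 ratio 0.30) and Olfml3 (-0.59) lay within 2-fold. Of 18 measured phagocyte activation genes, 13 were at least 2-fold higher and 0 lower (median 1.93). Spp1, which encodes the secreted matrix protein osteopontin, stood at 152 CPM [144 to 160] in sham and 33374 CPM [33310 to 33438] at 3 dpi, 219-fold higher. In sham 1.47% of these cells held a Spp1 UMI, so few cells set the sham level, and the log2 ratio of 7.69 was 11.31 in male- and 6.84 in female-derived cells. The galectin Lgals3 (14.0 and 1162 CPM), the growth factor Igf1 (2.97 and 189 CPM), the lipid carrier Apoe (1705 and 10731 CPM) and lipoprotein lipase Lpl (53.6 and 280 CPM) were also higher. The receptor Trem2 (2517 and 1524 CPM, log2 ratio -0.72) was within 2-fold.

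Cell cycle genes were higher in 3 dpi microglia-like cells in 18 of 20 cases (median log2 ratio 2.90). Mki67, a marker of proliferating cells, stood at 0.22 CPM in sham (2 UMIs) and 257 CPM at 3 dpi, a ratio of 1169 [324 to 9655]. Top2a, a topoisomerase of dividing cells, stood at 0.44 and 231 CPM, and Pclaf was at least 665-fold higher (0 UMIs in sham, 220 CPM at 3 dpi). Birc5 (247 CPM) and Ube2c (222 CPM) each had 1 UMI in sham, with ratios of 2246 [403 to 88720] and 2017 [362 to 79681]. Genes of glycolysis and hypoxia were higher in 11 of 15 (median 2.30), among them Pgk1 (50.9 and 421 CPM), Gapdh (601 and 3392 CPM) and Ldha (142 and 725 CPM). Oxidative phosphorylation genes were higher in 10 of 18 (median 1.14), for example Cox5a (139 and 549 CPM). Lipid uptake, storage and efflux genes were higher in 7 of 10 (median 1.28), among them the lipid droplet protein Plin2 (34.0 and 796 CPM), the scavenger receptor Msr1 (1.43 and 326 CPM) and the cholesterol exporter Abca1 (78.4 and 202 CPM). Of 7 iron and heme handling genes 4 were higher and 1 lower (median 1.22), and Hmox1, which degrades heme, was 19.1-fold higher (200.3 and 3834 CPM).

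Of 14 measured cytokines and chemokines, 5 were higher and 4 lower in microglia-like cells (median 0.72). The interferon-inducible chemokine Cxcl10 was higher (112 and 353 CPM). The chemokines Ccl3 (3984 and 874 CPM) and Ccl4 (6081 and 2144 CPM) and the cytokines Il1a (666 and 148 CPM) and Tnf (852 and 265 CPM) were lower at 3 dpi. Of 15 dissociation and immediate early genes, 14 were lower (median -2.74), among them Jun (7699 and 460 CPM), Egr1 (3243 and 222 CPM), Btg2 (3381 and 294 CPM) and Fos (4179 and 612 CPM). MHC class I genes were lower in 5 of 8 (median -1.16; B2m, 1667 and 758 CPM) and MHC class II genes in 2 of 4 (median -1.03). In the growth factor list (1 higher, 1 lower of 5, median 0.18) Igf1 was higher and Pdgfb (329 and 57.8 CPM) lower. The remaining genes highest by the fixed size rule were the matrix and cytoskeletal genes Fn1 (log2 ratio 6.79), Lgals1 (5.84), Vim (5.11) and Anxa2 (4.47). Fn1 is also a fixed monocyte/macrophage marker. Monocyte/macrophage was the 2nd class of the 3 dpi microglia-like clusters 5 and 10 (mean log2 folds 1.13 and 1.08, against 3.42 and 3.10 for microglia). The remaining lowest were the protease inhibitor gene Cst3 (51634 and 3029 CPM, 17.04-fold lower), the adhesion receptor Adgrg1 (-3.84), the fructose transporter Slc2a5 (-3.49), and the immediate early or quiescence-linked genes Ier5 (-3.66), Egr3 (-3.62), Klf4 (-3.54) and Klf2 (-3.46).

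The other lists measured in microglia-like cells were interferon response (3 higher, 0 lower of 6, median 0.997), complement (0 and 1 of 6, -0.40), cholesterol synthesis (0 and 2 of 7, -0.85), astrocyte reactivity (4 and 0 of 8, 1.18, led by Vim), extracellular matrix (3 and 1 of 4, 3.77, led by Fn1) and leukocyte adhesion (1 and 2 of 4, -1.12). Lists of other cell types had negative medians in these cells: myelin (0 and 13 of 13, -1.80), astrocyte homeostatic genes (0 and 4 of 4, -1.72), oligodendrocyte differentiation (0 and 3 of 4, -1.30) and blood-brain barrier (0 and 2 of 4, -0.997). Over members with any UMI, which counts members near 0 CPM, the medians were 0.043 for interferon response, 0.042 for complement, 0.198 for astrocyte reactivity, 0.384 for extracellular matrix, 0.018 for leukocyte adhesion, 0.663 for iron and heme handling, -0.449 for cholesterol synthesis, -0.016 for MHC class II, -0.437 for astrocyte homeostatic, -0.153 for differentiation and -0.393 for barrier genes. The astrocyte reactivity median was 0.539 in male-derived cells and 0.278 with 5% of UMIs subtracted as free RNA, where 2 rather than 4 genes were higher and the iron median was 1.98. With 1 CPM added, the medians were 5.66 for cell cycle, 2.22 for astrocyte reactivity, 5.23 for extracellular matrix, -2.40 for astrocyte homeostatic and -2.63 for myelin genes. Free RNA differed between the libraries in the same direction: the myelin gene Mag stood in microglia-like cells at 138 CPM in sham, 3.52% of the level in oligodendrocyte-like cells, and at 29.9 CPM at 3 dpi. Gpnmb (4.56%), Cxcl2 (7.16%), Ccl7 (7.13%), Ifitm3 (3.96%), Ifi27l2a (8.21%) and Cd74 (0.890%) stood in microglia-like cells at under 10% of the level in their highest class. Different clusters held the class in each library (cluster 1 with 2074 of 2184 sham cells, clusters 5 and 10 with 1280 and 868 of 2157 3 dpi cells), ribosomal genes took 14.3% and 18.4% of UMIs, and the median log2 ratio of all 6245 measured genes was -0.12.

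**Figure D2:**
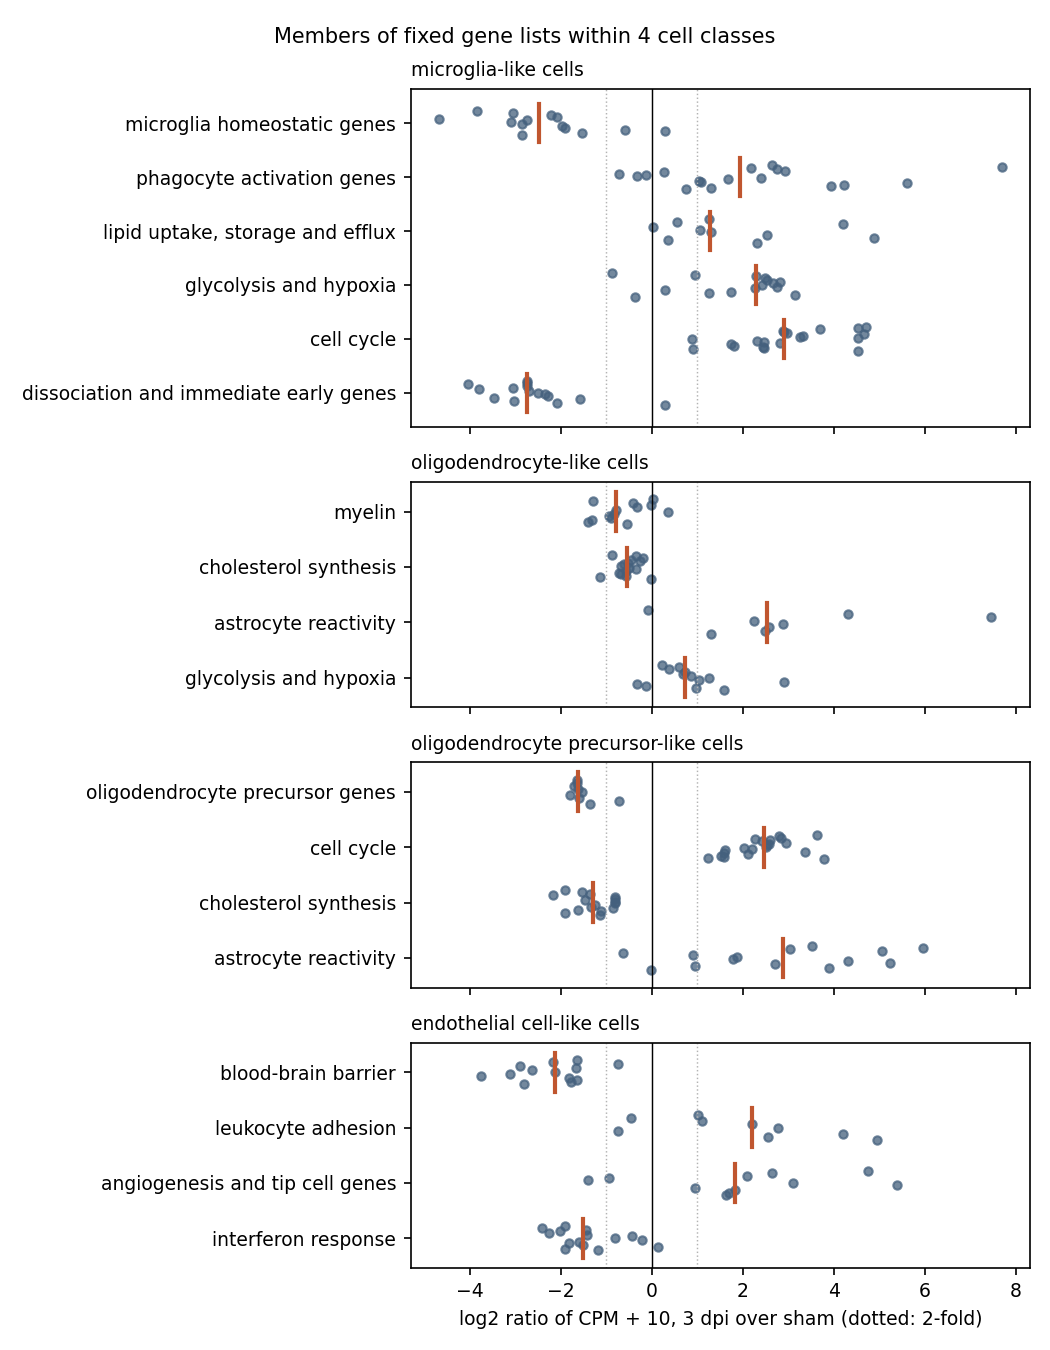
Log2 ratio of CPM, 3 dpi over sham, of each measured member (points) of selected fixed gene lists in the compared classes, 1 library per group, with the list median as an orange line and 2-fold as dotted lines. Other measured lists are not shown. Homeostatic genes in microglia-like cells have a median of -2.48 and blood-brain barrier genes in endothelial-like cells a median of -2.14.

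In oligodendrocyte-like cells, Serpina3n, a secreted protease inhibitor of the acute phase, stood at 12.7 CPM [11.6 to 13.8] in sham and 3970 CPM [3942 to 3998] at 3 dpi, 313-fold higher. The astrocyte reactivity list, which holds Serpina3n, was higher in 7 of 8 members and lower in 0 (median 2.52), with the hyaluronan receptor Cd44 (8.68 and 101 CPM) and the transcription factor Stat3 (72.1 and 192 CPM) among them. The complement component C4b (34.5 and 529 CPM) led a complement list of 4 with 4 higher (median 1.40), in which the C1q genes of phagocytes were the other 3 (C1qa at 110 CPM at 3 dpi against 7710 CPM in microglia-like cells). With free RNA subtracted, the complement lists of this and the other classes outside microglia-like cells kept fewer than 4 measured members. Of 13 myelin genes 3 were lower and 0 higher (median -0.79). The lower genes included Fa2h, a hydroxylase of myelin lipids (706 and 260 CPM), and Aspa, which releases acetate for lipid synthesis (723 and 283 CPM). Mbp (5263 and 5313 CPM) and Mag (3911 and 3856 CPM) lay within 2-fold (log2 ratios 0.01 and -0.02).

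Other highest genes of oligodendrocyte-like cells included the protease Klk8 (1.34 and 768 CPM), S100a10 (1.73 and 327 CPM), the synaptotagmin Syt4 (0.25 and 183 CPM) and the transcription factor Sox4 (3.39 and 197 CPM), whose log2 ratio of 3.95 was 2.89 with finer clusters. The lowest were the prostaglandin D synthase Ptgds (19569 and 1210 CPM, 16.2-fold lower), Jph4 (log2 ratio -3.16), C030029H02Rik (-3.04), Spock3 (-2.64), Clmn (-2.11) and Creb5 (-1.96). Phagocyte activation genes were higher in 11 of 13 (median 1.77), with the lysosomal membrane protein Cd63 at 265 and 2203 CPM and with Spp1 (919 CPM) and Lgals3 (519 CPM) at 2.57% and 8.77% of the level in their highest class. Vim (4.97%), Lgals1 (4.6%), Timp1 (1.3%) and Hmox1 (3.25%) were also under 10% of it. Extracellular matrix genes were higher in 5 of 6 (median 1.94), glycolysis and hypoxia genes in 4 of 13 (0.74; Ldha, 10.0 and 140 CPM) and MHC class I genes in 2 of 4 (0.92). Cholesterol synthesis genes were lower in 1 of 16 (median -0.55; Hmgcs1, 1033 and 554 CPM). Immediate early genes were higher in 2 of 16 and lower in 0 (median -0.14; Socs3, 24.2 and 237 CPM).

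The remaining lists in oligodendrocyte-like cells were lipid uptake (1 higher, 1 lower of 6, median 0.36), oxidative phosphorylation (0 and 0 of 18, 0.33), iron and heme handling (2 and 0 of 5, 0.08), astrocyte homeostatic genes (0 and 3 of 5, -1.20), differentiation (1 and 1 of 8, -0.10; Bcas1, 267 and 587 CPM) and blood-brain barrier (0 and 1 of 4, -0.35). With 5% of UMIs subtracted as free RNA, 6 rather than 11 phagocyte genes and 3 rather than 5 matrix genes were higher, and the medians of lipid uptake (-0.337) and immediate early genes (0.097) changed sign. Over members with any UMI the medians were 0.428 for astrocyte reactivity, 0.395 for complement, 0.484 for extracellular matrix, 0.361 for MHC class I and -0.282 for astrocyte homeostatic genes. With 1 CPM added the astrocyte reactivity and matrix medians were 4.54 and 3.94. Klk8 and Syt4 were among the 10 leading genes of cluster 14. Clusters 2, 6 and 8 held 1859, 1186 and 1136 of 4358 sham cells and clusters 11, 12 and 14 held 722, 648 and 472 of 1905 3 dpi cells, with 4.78% and 10.3% ribosomal UMIs.

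Oligodendrocyte precursor-like cells, the dividing progenitors of the lineage, had higher cell cycle genes at 3 dpi in 20 of 20 members (median log2 ratio 2.46). Mki67 stood at 21.0 and 376 CPM, Top2a at 56.9 and 453 CPM and Cdk1, the mitotic kinase, at 25.7 and 243 CPM. Astrocyte reactivity genes were higher in 10 of 14 and lower in 0 (median 2.87). The intermediate filament genes Vim (32.5 and 2624 CPM), Gfap (16.3 and 289 CPM) and Nes (10.2 and 156 CPM) were among them, as were Tm4sf1 (10.2 and 743 CPM), Serpina3n (21.0 and 1022 CPM) and the matrix protein gene Tnc, with 3 UMIs in sham (2.03 and 168 CPM). Precursor identity genes were lower in 8 of 9 (median -1.62). Pdgfra, the growth factor receptor of precursors, stood at 962 CPM [913 to 1013] in sham and 301 CPM [291 to 311] at 3 dpi, the proteoglycan Cspg4 at 566 and 173 CPM and C1ql1 at 1945 and 583 CPM, while Sox6 (log2 ratio -0.71) was within 2-fold.

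Cholesterol synthesis genes were lower in precursor-like cells in 11 of 16 (median -1.29), including the synthase Hmgcs1 (577 and 145 CPM). Genes of oligodendrocyte differentiation were lower in 4 of 9 (median -0.88), among them Gpr17 (428 and 107 CPM) and Neu4 (492 and 57.1 CPM), and the median was -2.48 with coarser clusters. Of 6 growth factors, Fgf2 (4.74 and 33.2 CPM), Pdgfa (68.4 and 178 CPM) and Hbegf (84.6 and 199 CPM) were higher and the angiogenic factor Vegfa (84.0 and 17.6 CPM) lower (median 0.82). Of 6 cytokines and chemokines 5 were higher (median 2.16), among them the monocyte attractant Ccl2 (7.45 and 152 CPM), at 10.1% of the level in its highest class, while Cxcl2 (0.67%) and Il1b (0.39%) were near the level of free RNA. With 5% of UMIs subtracted as free RNA, the cytokine and interferon lists of these cells kept fewer than 4 measured members. The other highest genes were Lgals1 (18.96 and 2864 CPM), S100a10 (21.0 and 1377 CPM) and Klk8, with 2 UMIs in sham (506 CPM at 3 dpi, ratio 374 [103 to 3088]). The lowest were the neuropeptide gene Tac1 (134 and 2.12 CPM), the proteoglycan Bcan (959 and 93.7 CPM), Cldn10 (log2 ratio -3.19), Caly (-3.17), Pcsk2 (-3.13) and C1ql2 (-3.11). Immediate early genes were lower in 11 of 15 (median -1.92; Jun, 4530 and 1237 CPM) and astrocyte homeostatic genes in 6 of 8 (median -1.24; Aldoc, 752 and 100.01 CPM).

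The other lists in precursor-like cells were phagocyte activation (8 higher, 1 lower of 14, median 1.31), extracellular matrix (5 and 1 of 8, 1.81), interferon response (2 and 0 of 4, 0.60), complement (3 and 0 of 4, 1.08, of which C1qa and C1qb stood at 105 and 103 CPM at 3 dpi against 7710 and 6062 CPM in microglia-like cells), MHC class I (0 and 2 of 6, -0.41), lipid uptake (1 and 1 of 7, -0.06), glycolysis and hypoxia (5 and 1 of 15, 0.51), oxidative phosphorylation (0 and 0 of 18, 0.26), iron and heme handling (3 and 0 of 6, 0.95), microglia homeostatic genes (1 and 0 of 5, -0.32), blood-brain barrier (0 and 3 of 6, -1.10) and myelin (0 and 10 of 12, -1.88). Mag stood in these cells at 118 CPM in sham, 3.01% of the level in oligodendrocyte-like cells, and at 23.0 CPM at 3 dpi, and with 5% of UMIs subtracted as free RNA 1 rather than 10 myelin genes was lower and 4 rather than 8 phagocyte genes were higher. With doublets kept, 8 cytokines, 6 complement and 8 matrix genes were higher, and 3 rather than 6 astrocyte homeostatic genes were lower with median-of-ratios scaling. The log2 ratio of Tm4sf1 (5.22) was 4.28 with doublets kept and 6.22 with free RNA subtracted. That of Serpina3n (5.06) was 5.83 in male-derived cells, and those of Caly and C1ql2 were -2.57 and -2.52 with coarser clusters. Coarser clusters gave a myelin median of -3.37, and free RNA subtraction gave -0.634 for myelin, 0.556 for phagocyte and 1.55 for iron genes. The cell cycle and complement medians were 3.29 and 1.76 in female-derived cells, and the interferon and iron medians 1.42 and 1.98 with median-of-ratios scaling. The growth factor median was -0.098 with coarser clusters, the microglia homeostatic median 0.626 with median-of-ratios scaling, and the lipid uptake median from 0.035 to 0.784 in 5 of the other settings. Over members with any UMI the medians were 0.379 for cytokines, 0.969 for astrocyte reactivity, 0.659 for extracellular matrix, 0.626 for phagocyte activation, 0.347 for iron and heme handling, 0.549 for complement, 0.356 for growth factors and -0.382 for barrier genes. With 1 CPM added they were 4.29 for cytokines, 3.94 for astrocyte reactivity, 4.09 for extracellular matrix and -1.69 for barrier genes. Cluster 20 held 270 of 280 sham cells and cluster 9 held 866 of 873 3 dpi cells, with 6.99% and 18.2% ribosomal UMIs and a median log2 ratio of -0.26 over all 8174 measured genes.

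In endothelial-like cells, blood-brain barrier genes were lower at 3 dpi in 12 of 13 members and higher in 0 (median log2 ratio -2.14). Cldn5, the main claudin of brain endothelial tight junctions, stood at 8920 CPM [8843 to 8998] in sham and 2825 CPM [2784 to 2865] at 3 dpi. The organic anion transporter Slco1a4 was 14.5-fold lower (2038 [2001 to 2075] and 141 [132 to 150] CPM), the lipid transporter Mfsd2a 8.89-fold lower (389 and 43.7 CPM), the efflux pump Abcb1a 6.48-fold lower (1098 and 169 CPM) and the glucose transporter Slc2a1 3.20-fold lower (2521 and 789 CPM). Tjp1 (log2 ratio -0.75) was within 2-fold. Leukocyte adhesion genes were higher in 7 of 9 and lower in 0 (median 2.19). Ackr1, a chemokine-binding receptor of venules, had 2 UMIs in sham and 180.5 CPM at 3 dpi, a ratio of 521 [144 to 4303]. Lrg1 had 3 UMIs in sham and 314 CPM at 3 dpi, a ratio of 604 [206 to 2932], and the adhesion molecules Icam1 (147 and 305 CPM) and Vcam1 (40.9 and 98.4 CPM) were also higher.

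Angiogenesis and tip cell genes were higher in endothelial-like cells in 8 of 11 and lower in 1 (median 1.82). The peptide ligand Apln stood at 4.16 and 369 CPM, Angpt2, which loosens vessel walls, at 22.5 and 128 CPM, and the placental growth factor Pgf at 410 CPM at 3 dpi with 0 UMIs in sham, at least 788-fold higher. The Pgf bound depended on the choice of cells. The ratio was 38.0 [31.0 to 47.2] with cluster 19, left without a class, counted as endothelial-like (95 sham UMIs) and 341 [185 to 711] with doublets kept (10 sham UMIs). The VEGF receptor Kdr was lower (747 and 277 CPM). Extracellular matrix genes were higher in 10 of 12 (median 1.77), with the basement membrane collagens Col4a1 (389 and 1288 CPM) and Col4a2 (295 and 933 CPM). Cell cycle genes were higher in 17 of 20 (median 2.38; Mki67, 2.25 and 98.9 CPM). Interferon response genes were lower in 11 of 15 and higher in 0 (median -1.51), among them the regulator Irf7 (167 and 26.8 CPM), Ifit1 (204 and 30.4 CPM) and Isg15 (185 and 41.6 CPM). MHC class I genes were lower in 6 of 8 (median -1.11; B2m, 944 and 418 CPM). Glycolysis and hypoxia genes were higher in 8 of 15 and lower in 1 (median 1.13), growth factors higher in 3 of 6 (0.96; Bmp2, 1.04 and 36.8 CPM, and Pdgfa, 42.1 and 183 CPM) and cytokines in 6 of 8 (1.93; Cxcl1, 19.6 and 144 CPM). Of 8 iron and heme genes 4 were higher and 2 lower (median 0.54), the latter the iron exporter Slc40a1 (259 and 41.6 CPM) and the transferrin receptor Tfrc (198 and 61.0 CPM).

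Other highest genes of endothelial-like cells included AA467197 (0 UMIs in sham, 731 CPM at 3 dpi, at least 1405-fold higher), S100a6 (13.7 and 1622 CPM) and Lgals1 (4.51 and 392 CPM). The log2 ratio of Lgals1 (4.79) was 3.32 with cluster 19 and that of S100a6 (6.11) was 5.13 with doublets kept. The other lowest were the anion transporter Slc22a8 (518 and 17.9 CPM, 29.0-fold lower), Spock2 (log2 ratio -3.29), Gkn3 (-3.34), and AY036118 (-3.88) and Gm42418 (-3.58), which overlap ribosomal RNA sequence. With the mean of cells, the log2 ratios of Slc22a8 (-4.24), AY036118, Slco1a4 (-3.76), Gm42418, Gkn3 and Spock2 were -3.32, -2.92, -2.95, -2.75, -2.26 and -2.44, and Spock2 was -2.65 in female-derived cells. Immediate early genes were lower in 11 of 16 (median -1.24; Jun, 4498 and 991 CPM). The remaining lists were phagocyte activation (9 higher, 1 lower of 13, median 1.46), astrocyte reactivity (7 and 4 of 14, 1.04), complement (2 and 1 of 4, 1.03, the higher being C1qb and C1qc at 112 and 58.3 CPM at 3 dpi against 6062 and 4147 CPM in microglia-like cells), lipid uptake (1 and 0 of 7, 0.60), cholesterol synthesis (0 and 1 of 11, -0.79), oxidative phosphorylation (0 and 0 of 18, 0.29), oligodendrocyte differentiation (0 and 1 of 4, -0.62) and myelin (0 and 12 of 12, -1.98). Mag stood in these cells at 124 CPM in sham, 3.16% of the level in oligodendrocyte-like cells, and at 18.2 CPM at 3 dpi, and Ccl2 (4.86%), Timp1 (4.8%) and Hmox1 (3.48%) stood at under 10% of the level in their highest class.

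With doublets kept, the medians of endothelial-like cells were -0.11 for complement, with 0 genes higher, 0.036 for lipid uptake, -1.38 for cholesterol synthesis, -2.13 for differentiation and -4.20 for myelin. In these cells 2 or 3 rather than 6 MHC class I genes were lower with doublets kept, in male-derived cells or with other scalings, while 7 or 5 rather than 11 immediate early genes were lower with median-of-ratios scaling or the mean of cells. With 5% of UMIs subtracted as free RNA, 2 rather than 9 phagocyte genes, 3 rather than 6 cytokines and 6 rather than 10 matrix genes were higher, and the phagocyte median was 0.033. Over members with any UMI the medians were 0.747 for phagocyte activation, 0.510 for cytokines, 0.421 for complement, 0.345 for growth factors and 0.282 for astrocyte reactivity, and with 1 CPM added 5.01 for cell cycle, 3.89 for leukocyte adhesion, 3.17 for extracellular matrix, 3.09 for cytokines and -2.71 for myelin genes. Cluster 4 held 1396 of 1405 sham cells and cluster 18 held 354 of 379 3 dpi cells, with 10.1% and 24.5% ribosomal UMIs and a median log2 ratio of -0.26 over 7031 measured genes. The cilia, neutrophil granule and lymphocyte cytotoxicity lists had fewer than 4 measured members in each of the 4 compared classes.

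The 3rd comparison asked which classes held cycling cells, defined by at least 2 UMIs of 10 mitotic genes after each cell was thinned to 1000 UMIs. Microglia-like cells were cycling in 699 of 2153 cells at 3 dpi (32.5% [30.5 to 34.5]) and in 0 of 2104 in sham, which allows up to 0.143%. Macrophage-like cells of the same 3 dpi library were cycling in 14 of 3458 cells (0.405% [0.222 to 0.678]). Precursor-like cells were cycling in 3.24% [1.49 to 6.06] of sham and 45.5% [42.1 to 48.8] of 3 dpi cells. Endothelial-like cells were cycling in 0.074% [0.002 to 0.412] and 17.6% [13.8 to 21.8], oligodendrocyte-like cells in 0.093% [0.025 to 0.238] and 1.80% [1.24 to 2.52]. At 3 dpi, 23.9% [20.6 to 27.4] of fibroblast-like and 0.743% [0.273 to 1.61] of neutrophil-like cells were cycling. Within classes the shares differed between clusters, counted over both libraries in a separate thinning. Of the microglia-like clusters, cluster 10 had 627 of 868 cells cycling (72.2% [69.1 to 75.2]) and cluster 5 had 75 of 1287 (5.83% [4.61 to 7.25]). Of the oligodendrocyte-like clusters, cluster 14, with 0 oligodendrocyte markers among its 10 leading genes, had 28 of 413 (6.78% [4.55 to 9.65]), and clusters 11 and 12 had 0.690% and 0.154%. Of the clusters left without a class, cluster 17, with macrophage and dendritic markers, had 67 of 406 cycling (16.5% [13.02 to 20.5]) and cluster 15 had 34 of 470 (7.23% [5.06 to 9.96]). With cluster 17 counted as macrophage-like, 2.23% of macrophage-like cells were cycling. Unthinned, the sham and 3 dpi shares were 0.092% and 73.9% in microglia-like, 4.64% and 73.3% in precursor-like, 0.214% and 45.1% in endothelial-like and 0.390% and 10.3% in oligodendrocyte-like cells, and at 3 dpi 7.31% in macrophage-like, 59.2% in fibroblast-like and 1.02% in neutrophil-like cells. Cells too shallow to thin numbered 80 and 4 in microglia-like, 2 and 2 in precursor-like, 55 and 9 in endothelial-like, 50 and 72 in oligodendrocyte-like cells and, at 3 dpi, 15, 3 and 668 in macrophage-, fibroblast- and neutrophil-like cells.

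**Figure D3:**
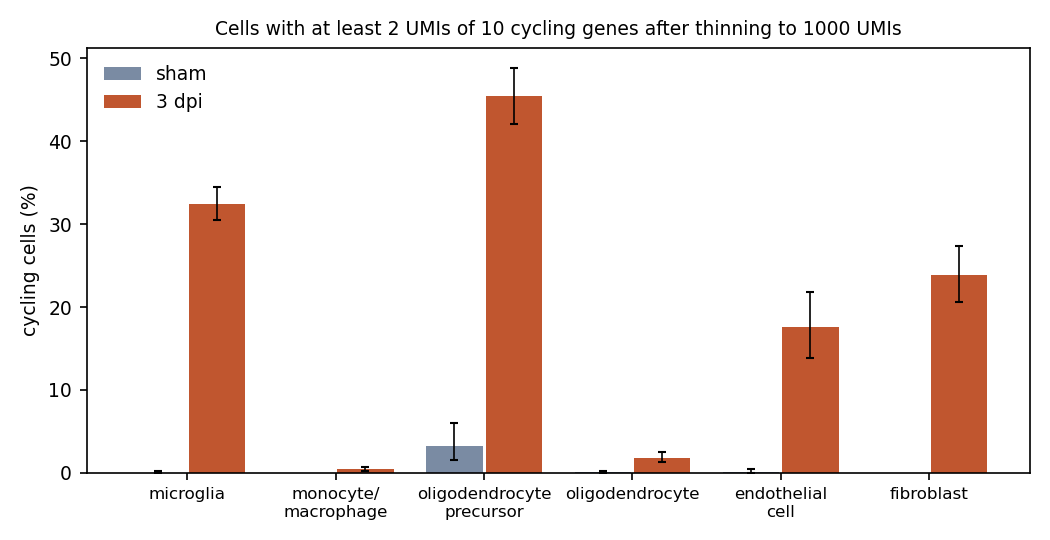
Percent of cells with at least 2 UMIs of the 10 cycling genes after thinning to 1000 UMIs, per class in the sham and 3 dpi libraries, 1 library per group, with 95% Clopper-Pearson intervals as bars. Sham bars of macrophage- and fibroblast-like cells, with fewer than 50 cells, are left out, and 3 dpi shares are 32.5% in microglia-like and 0.405% in macrophage-like cells.

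Cells with Y-linked UMIs and no Xist were taken as male-derived and those with Xist and no Y-linked UMIs as female-derived, so that the mice of each sex in a pool could be compared. Male-derived cells were 43.3% [42.1 to 44.6] of sexed sham cells and 51.0% [49.9 to 52.1] of sexed 3 dpi cells. Among microglia-like cells the male share was 36.8% in sham and 48.5% at 3 dpi, among precursor-like cells 38.3% and 52.8%, and among endothelial-like cells 40.0% and 58.8%. These shares depended on depth. With each cell thinned to 1000 UMIs they were 20.4% [17.7 to 23.2] and 21.7% [18.1 to 25.6] in microglia-like cells. They were 19.2% [12.8 to 27.1] and 29.5% [23.1 to 36.5] in precursor-like and 28.9% [24.9 to 33.3] and 36.4% [24.9 to 49.1] in endothelial-like cells, and the intervals overlapped in each class. Of all cells thinned and sexed, 25.3% [23.9 to 26.8] in sham and 31.0% [29.2 to 32.9] at 3 dpi were called male. The median log2 ratio of the homeostatic list in microglia-like cells was -2.58 in male- and -2.32 in female-derived cells, and that of the barrier list in endothelial-like cells -2.30 and -1.78.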

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

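The tests of free RNA in Cd63 and the cathepsins, of myeloid doublets, of handling and of cycling cells were chosen only after the results were seen, while the tests of free RNA in Spp1, Lgals3, Gpnmb, Tyrobp and Cd68 and of activation in sham microglia were written before.

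3 clusters without a class, outside the comparisons of classes, held a larger share of cells at 3 dpi than in sham, and their genes are list members picked after their values were seen. Cluster 15, which carried both microglia and macrophage markers, held 4.04% [3.70 to 4.40] of 3 dpi cells and 0 of 9306 sham cells, with Spp1 at 59992 CPM, Hmox1 at 10451 CPM and Lpl at 423 CPM. Cluster 17, with dendritic cell markers among its leading genes, held 3.34% [3.03 to 3.68] of 3 dpi cells and 1 sham cell, with the antigen presentation genes Cd74 at 13105 CPM and H2-Aa at 5633 CPM and the cytokine Il1b at 2499 CPM. Cluster 24, with ependymal, astrocyte and pericyte markers, held 0.727% [0.583 to 0.895] of 3 dpi and 0.333% [0.226 to 0.472] of sham cells, with Vim at 13191 CPM, Gfap at 1679 CPM and the cilia regulator Foxj1 at 148 CPM at 3 dpi, and its 31 sham cells were too few to compare genes. No explanation was tested for these clusters.

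At 3 dpi, 11 of 13, 8 of 14 and 9 of 13 phagocyte genes were at least 2-fold higher in oligodendrocyte-, precursor- and endothelial-like cells, and 6, 4 and 2 with free RNA subtracted, where the endothelial median log2 ratio was 0.033. For Spp1, Lgals3, Gpnmb, Tyrobp and Cd68 the level in these classes over the whole-library level was 1.33 times that of the C1q genes of myeloid cells, a value that free RNA needs, although Lgals3 in oligodendrocyte-like (6.00) and precursor-like (3.33) and Gpnmb in precursor-like cells (2.86) were above the bound of 2, and Fabp5, a list member in no tested group, was at 35.4, 5.39 and 1.09 in the 3 classes. For Cd63, Ctsb, Ctsd and Ctsl the same ratio was 6.24 in oligodendrocyte-like cells. There Cd63 at 32.3 and Ctsb at 8.28 argue against free RNA as the whole source of their 3 dpi level, while Ctsl at 4.20 lay near and Ctsd at 2.53 below the bound of 4. In precursor- and endothelial-like cells the ratio was 3.08, between the bounds of 2 and 4 that would decide. Ctsb and Ctsl were not among the 2-fold higher genes of precursor-like cells, nor Ctsl among those of endothelial-like cells. These ratios use levels at 3 dpi and not the rise over sham, so they do not tell the source of a rise. The test of Cd63 and the cathepsins first ran over the 3 classes together, gave 3.48, and was split after this value was seen. The 5% of cells with most C1q UMIs held 27.0% of them (upper bound over resampled cells 31.2), more than by depth alone (15.5 to 18.5) and less than the 50% that doublets with myeloid cells would need, so remaining doublets stay open, as does expression in these cells after injury.

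Immediate early genes and Ccl3, Ccl4, Il1a and Tnf were lower in microglia-like cells at 3 dpi. A handling difference that acts on all classes alike would lower the immediate early list in oligodendrocyte-like cells by a similar amount, but its median log2 ratio was -0.135 there (0.097 with free RNA subtracted) against -2.74 in microglia-like, -1.92 in precursor-like and -1.24 in endothelial-like cells, which argues against it. Dissociation that activates some classes more than others in the sham library may still account for the pattern: within sham microglia-like cells, the 4 cytokines were 1.22 times as high in the 701 cells with most immediate early UMIs as in the 701 with fewest, between the bounds of 1.1 and 1.5 set in advance. At 3 dpi that ratio was 2.33 over 717 cells each. Activation in sham, handling of this kind and the injury cannot be told apart with 1 library per group.

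Microglia-like cells at 3 dpi were often cycling, beside few cycling macrophage-like cells. Free RNA of cycling cells would reach all clusters alike, but 0.405% of macrophage-like cells were cycling (2.23% with cluster 17, above the bound of 2%) against 16.5% of cluster 17 and 72.2% of microglia-like cluster 10, which argues against it as the whole source. Doublets with another cycling cell would raise barcodes with both Xist and Y-linked UMIs, which were 5.16% of cycling (30 of 582) and 3.76% of other microglia-like cells (44 of 1170). Of the removed 3 dpi doublets only 24.7% held both, so the test cannot exclude doublets as the source of part of the cycling cells. The ratio of cycling over other cells was 1.37 [0.832 to 2.23], with an upper bound below the 3-fold set for doublets after the results were seen. Cycling cells were deeper (16116 and 12249.5 median UMIs), which biases that ratio upward, and an earlier form of the test at 4000 UMIs per cell gave 1.34 [0.393 to 4.22] and, over 100 draws, from 0.215 to 5.23, which decides little. More division in some microglia than in most macrophages at 3 days is a hypothesis, found and tested on the same 1 library, in which batch and injury cannot be told apart, and it rests on how clusters were named, since microglia-like cluster 5 had 5.83% cycling and cluster 17, with macrophage and dendritic markers, had more.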

How the results depend on the processing

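Counting clusters 15, 17 and 19 in a class and calling sex at equal depth were chosen only after the data were seen. The other settings were fixed before. No paired analysis was possible and no value has a test because each group was 1 library. A value is called the same when it stayed within its counting interval, a count when within 1.5 times. By this measure 515 of 536 counts of list members, 38 of 60 ratios of class shares, 22 of 39 cycling shares, 24 of 50 medians of a class's own identity list, 539 of 911 other list medians and 430 of 756 named-gene ratios were the same. In the others the value moved. The direction turned for 1 class share and, among list medians of at least 1 in size, for 2. Medians below 1 in size changed sign in 10 cases over 6 lists. None of the 60 named-gene ratios turned direction, but 35 shifted by more than 1.5-fold with 1 CPM added and 15 in other settings (19 values). Where values moved, the cause was not tested, except that subtraction of free RNA and added clusters change the sums by construction. Counting intervals are narrow at this depth, so small shifts count as moved. Filters on mitochondrial UMIs were not run, as the tables held no mitochondrial genes. The pericyte share in male-derived cells and 17 list medians, 14 of them with free RNA subtracted, could not be given because fewer than 4 members or no cells were left.

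Class shares were compared as log2 ratios of 3 dpi over sham, with main values of -0.40 for microglia-like, 8.06 for macrophage-like, 6.24 for neutrophil-like, -1.57 for oligodendrocyte-like, 1.26 for precursor-like, -2.27 for endothelial-like and 4.69 for fibroblast-like cells. With the stricter cell filter, microglia gave -0.29 and neutrophils 5.41. With doublets kept, microglia gave -0.056. At resolution 2.0, oligodendrocytes gave -1.67. At resolution 0.5, microglia gave -0.10, macrophages 5.54, oligodendrocytes -1.74 and precursors 0.98. In male-derived cells, microglia gave 0.13, which turned direction, macrophages 6.70, neutrophils 4.54, oligodendrocytes -1.72, endothelial cells -1.68 and fibroblasts 5.66. In female-derived cells, microglia gave -0.12, macrophages 9.16, oligodendrocytes -1.46 and precursors 1.02. With sex called after thinning to 1000 UMIs, microglia gave -0.589 in male- and -0.293 in female-derived cells, where the direction did not turn. Cluster 15 as microglia gave -0.10 for microglia, and cluster 19 as endothelial gave -2.56 for endothelial cells.

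Cycling cells were compared as percent of a class at 3 dpi, with main values of 32.5 in microglia-like, 45.5 in precursor-like, 17.6 in endothelial-like and 0.405 in macrophage-like cells. With doublets kept, microglia gave 28.2 and macrophages 0.761. At resolution 0.5 they gave 29.2 and 0.947. In male-derived cells, microglia gave 37.9 and precursors 52.9, and in female-derived cells microglia gave 30.1. Cluster 15 as microglia gave 29.2, and cluster 17 as macrophages 2.23. Unthinned shares were 73.9, 73.3, 45.1 and 7.31 in the order of the main values, and shares at 3 UMIs were 22.9, 36.7, 11.1 and 0.029.

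Identity lists, which share genes with the markers that named the classes, were compared by their median log2 ratio. The homeostatic list in microglia-like cells was -2.48, and -2.68 with doublets kept, -2.65 at resolution 0.5, -2.58 in male- and -2.32 in female-derived cells, -2.65 with cluster 15, -2.33 with median-of-ratios scaling, -2.28 with the mean of cells and -2.53 with 1 CPM added. The myelin list in oligodendrocyte-like cells was -0.79, and -0.77 at resolution 0.5, -0.83 in male- and -0.68 in female-derived cells, -0.76 with median-of-ratios scaling, -0.82 with the mean of cells and -0.75 with free RNA subtracted. The precursor list was -1.62, and -1.56 at resolution 2.0 and with response genes kept for clustering, -1.05 at resolution 0.5, -1.52 in female-derived cells, -1.30 with median-of-ratios scaling and -1.40 with the mean of cells. The barrier list in endothelial-like cells was -2.14, and -1.80 with doublets kept, -2.3 in male- and -1.78 in female-derived cells, -1.92 with cluster 19, -1.82 with median-of-ratios scaling and -1.84 with the mean of cells.

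Counts of list members refer to ratios of at least 2-fold. With doublets kept, 8 cytokines, 6 complement and 8 matrix genes were higher in precursor-like cells (main 5, 3 and 5), and in endothelial-like cells 0 complement genes were higher (main 2), 2 MHC class I genes lower (main 6) and the complement median was -0.11 (main 1.03), which turned direction. In endothelial-like cells 3 MHC class I genes were lower among male-derived cells, 1 complement gene was higher among female-derived cells and 0 with cluster 19. With median-of-ratios scaling, 3 astrocyte homeostatic genes were lower in precursor-like cells (main 6), and 2 MHC class I and 7 immediate early genes were lower in endothelial-like cells (main 6 and 11). With the mean of cells the last were 2 and 5. With 5% free RNA subtracted, 2 astrocyte reactivity genes were higher in microglia-like cells (main 4). In oligodendrocyte-like cells 6 phagocyte and 3 matrix genes were higher (main 11 and 5). In precursor-like cells 4 phagocyte genes were higher (main 8) and 1 myelin gene was lower (main 10). In endothelial-like cells 2 phagocyte genes, 3 cytokines and 6 matrix genes were higher (main 9, 6 and 10). With members of any UMI, the leukocyte adhesion median of microglia-like cells was 0.018 (main -1.12), which turned direction.

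Of 78 list medians, 23 shifted by more than 1.5-fold over members with any UMI, where members near 0 CPM pull medians toward 0, and 16 did with 1 CPM added, where they do the reverse. The sign changes below 1 in size were in precursor-like cells for lipid uptake (main -0.061, 0.784 with doublets kept, 0.065 at resolution 0.5, 0.035 in male-derived cells, 0.190 with median-of-ratios scaling and 0.221 with any UMI), growth factors (main 0.824, -0.098 at resolution 0.5) and microglia homeostatic genes (main -0.322, 0.626 with median-of-ratios scaling). With free RNA subtracted, oligodendrocyte-like cells gave -0.337 for lipid uptake (main 0.362) and 0.097 for immediate early genes (main -0.135), and with any UMI microglia-like cells gave 0.042 for complement (main -0.402).

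Outside the 1 CPM setting, these log2 ratios of named genes shifted by more than 1.5-fold. With the mean of cells, Spp1 in microglia-like cells was 8.71 (main 7.69), and 6 endothelial genes were from -3.32 (Slc22a8, main -4.24) to -2.26 (Gkn3, main -3.34). Spp1 was 11.31 in male- and 6.84 in female-derived cells. With doublets kept, Tm4sf1 in precursor-like cells was 4.28 (main 5.22) and S100a6 in endothelial-like cells 5.13 (main 6.11). With cluster 19, Pgf was 4.34 (main 5.39) and Lgals1 3.32 (main 4.79). At resolution 2.0, Sox4 was 2.89 (main 3.95). The others were Tm4sf1 with free RNA subtracted, Serpina3n and Spock2 in cells of 1 sex, and Caly and C1ql2 at resolution 0.5.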

Other observations

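No test is reported in this part, and its genes are list members picked after their values were seen. Neutrophil-like cells of the 3 dpi library, a class too small in sham to compare, carried the inflammatory cytokine Il1b at 8721 CPM, the neutrophil attractant Cxcl2 at 9842 CPM, Tnf at 829 CPM and the iron-binding granule protein Lcn2 at 2378 CPM. In the same library macrophage-like and microglia-like cells had Spp1 at similar levels (35769 and 33374 CPM). Macrophage-like cells had more of the lysosomal glycoprotein gene Gpnmb (1688 and 77.0 CPM), the fatty acid binding protein Fabp5 (11188 and 1371 CPM), the scavenger receptor Cd36 (223 and 51.2 CPM), Vegfa (119 and 5.87 CPM) and the monocyte attractant Ccl7 (404 and 49.4 CPM). Microglia-like cells had more Igf1 (189 and 31.2 CPM), Lpl (280 and 35.3 CPM), Cxcl10 (353 and 13.2 CPM), Ccl12 (594 and 63.9 CPM), Tnf (265 and 20.8 CPM) and Pdgfb (57.8 and 4.46 CPM).

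Macrophage-like cells fell into clusters 0 and 7 at 3 dpi (2335 and 1138 cells). Cluster 0 had higher Spp1 (41459 and 11424 CPM), Gpnmb (1976 and 455 CPM) and Fabp5 (13268 and 2289 CPM), and cluster 7 higher Il1b (1783 and 162 CPM) and Cxcl2 (2407 and 291 CPM). Fibroblast-like cells at 3 dpi carried the matrix genes Sparc (4979 CPM), Timp1 (2886 CPM) and the collagen cross-linking enzyme Lox (689 CPM), with Igf1 at 229 CPM and the neutrophil attractant Cxcl1 at 418 CPM. T or NK cell-like cells carried the chemokine Ccl5 (2564 CPM), the cytotoxic protease Gzmb (265 CPM) and the checkpoint receptor Ctla4 (159 CPM) in 79 cells, and B cell-like cells Cd74 (12649 CPM) in 90 cells. Of sexed fibroblast-like cells at 3 dpi, 373 of 499 (74.7% [70.7 to 78.5]) were male-derived, against 51.0% of all sexed cells of that library and 54.9% of microglia-like cluster 10, which had a similar median depth (16050 and 16361.5 UMIs). This share was not computed at equal depth, where the male share of 3 dpi microglia-like cells was 21.7% rather than 48.5%. The call also depends on how much Xist and Y-linked RNA a class holds, and sham held 19 fibroblast-like cells. Barcodes with both Xist and Y-linked UMIs were 14.5% of sham oligodendrocyte-like cells and 22.2% of cluster 19.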
